A study of Rattus norvegicus with 54 samples.

How the data were processed

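RNA sequencing was done on lung and right ventricle of Sprague Dawley rats that lived from conception to 6 weeks of age in a hypobaric chamber at a simulated altitude of 9000 feet (equivalent to 15% inspired oxygen), named H-H in the labels, or in room air, named RA-RA. The series holds 54 libraries, 29 of lung and 25 of right ventricle. Per the labels, parents were acclimated from 7 weeks of age and bred at 10 weeks, and pups were weaned at day 21. Each treatment held 2 litters, taken from the animal names: 3HH and 4HH at altitude, 4RARA and 6RARA in room air. Litter is therefore nested in treatment, and the 4 litters are the independent exposures.

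Per the submitters' processing notes, poly(A) libraries were prepared with the KAPA mRNA HyperPrep kit and sequenced on a HiSeq4000. Reads were checked with FastQC and MultiQC 0.11.5, mapped with STAR 2.5 to the UCSC rn6 genome, and counted per gene with featureCounts 1.5.1 from the Subread package. The deposited read counts are raw counts per gene, per the file headers, for the genes that the authors kept: 12650 in the lung table and 12199 in the right ventricle table. Their filter is not stated. The deposited log2 fold change of H-H over RA-RA and the deposited p-value and false discovery rate came from edgeR, per the submitters' processing notes, with covariates and version not stated. They were used only beside the values computed here. The other deposited quantities, which the authors gave per library, are mapping statistics, library batch and comments of the sequencing core, per the file headers. They served as library checks and as alternatives. The deposited log2 RPKM columns were not used here. Gene symbols and rn6 coordinates are those of the deposited tables. A number stood in place of the symbol in 22 lung and 21 right ventricle table entries, which were treated as unnamed.

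Total counts ranged from 1028679 to 23902634 per lung library and from 6116006 to 16326512 per right ventricle library. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the groups compared, with a minimum count of 10 and a minimum total of 15. Libraries were scaled by TMM. Dispersions were estimated with estimateDisp, and a quasi-likelihood model (glmQLFit with robust=TRUE, then glmQLFTest) was fitted with treatment and sex. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Adjusted p values follow Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Unless another tool is named, an adjusted p of a gene is from this edgeR test. CPM values are scaled by TMM and given as mean ± standard deviation (SD).

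The comparisons were H-H against RA-RA in each tissue, male against female in each tissue, the interaction of sex and treatment in each tissue, the 2 litters of each treatment against each other in each tissue, and the interaction of tissue and treatment. The last was fitted to all 54 libraries, with sex within tissue. The replicate block, an edgeR fit with animal as a block over the animals that gave both tissues, was an alternative for it. Across treatments, a shared animal number does not pair 2 rats, because they come from different litters, so no pairing by number was fitted there. Lung and right ventricle libraries of one name were compared as a pair: over genes, deviations from the treatment mean correlated at a mean r of 0.25 within 25 named pairs and −0.0104 with other animals of the same treatment. Centring on the treatment mean itself holds the latter value small. Litter was not removed, so the 0.25 does not tell a shared animal from a shared litter.

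Gene lists were fixed before the data were examined, and 29 were tested in each tissue. Common to both were lists of HIF target genes, glycolysis, fatty acid oxidation, the nuclear-encoded respiratory chain, vasoactive signalling, BMP and TGF-beta signalling, pulmonary hypertension risk genes, extracellular matrix, the cell cycle, the circadian clock, immediate early genes, heat shock and unfolded protein response, antioxidant and NRF2 targets, cholesterol synthesis, interferon response and MHC genes of the RT1 complex. Markers of endothelium, smooth muscle, erythroid cells, B and plasma cells, T and NK cells, neutrophils, macrophages and monocytes, and mast cells, and of thymus, skeletal muscle and fat, were also tested in both. Markers of alveolar type 1, alveolar type 2, airway epithelial and cardiac muscle cells were tested in lung. The hypertrophy and fetal gene programme, sarcomere and calcium handling, atrial cardiomyocyte markers and lung epithelial markers were tested in right ventricle. Mitochondrially encoded transcripts were not analysed here as a list, since the tables hold none of them. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 29 lists of a tissue.

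Named genes were chosen by a rule fixed before the data were examined. It took the 5 largest rises and the 5 largest falls among called genes with a symbol, a mean log2 CPM of at least 1, 1 sign in both sexes, and both H-H litter means on the same side of both RA-RA litter means. It also took the 2 members of lowest p of each list, of which those of lists with a called member or a called list test are given, and those of the HIF and glycolysis lists. For the tissue interaction it took the 5 largest differences of each sign, for sex the 5 lowest p outside X and Y, and for litters the 5 lowest p. A gene named by another criterion is said to be chosen after its values were seen.

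The edgeR fits were tested on simulated counts for the same libraries with 200 changed genes. Each library was drawn independently with no litter effect, so the false calls below do not apply to litters nested in treatment. In the lung comparison 52% of 100 genes changed 1.5-fold and 85% of 100 changed 2-fold were called, with 6 false calls, and in the right ventricle comparison 45% and 75%, with 3 false calls. For the tissue interaction the shares were 15% and 50%, with 0 false calls, against 65 calls in all.

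Alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, median-of-ratios size factors, library size only, other filters on low counts, a fit without sex, RNA integrity number (RIN) as a covariate or of at least 7, robust=FALSE, limma voom with litter as a random effect, counts summed per litter, leaving out each litter, each sex alone and a 1.5-fold minimum. The run sheet marks the 2 libraries of animal 3HH28 as swapped, with incorrect RIN, and its values are the reverse of the labelled 9.9 (lung) and 8.3 (right ventricle), which were used. For the tissue interaction they also included animal as a random effect and TMM within each tissue. Chosen after seeing the data were library batch as a covariate, fits within batch 1 and batch 2, voom with quality weights, fits without libraries whose median Spearman correlation with the others of their tissue lay under 0.93, fits without animal 4HH37, fits of animals with both tissues without an animal block, gene list tests with each litter left out, and the clock ratio of the other tissue as a covariate, which is log2 Arntl minus log2 Dbp with a prior count of 2. Random splits of the samples, at most 100 per comparison, were fitted in the same way. Permutation and other tests are two-sided.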

Results

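Gene expression was measured in lung from 14 altitude rats (H-H, 8 of litter 3HH and 6 of litter 4HH) and 15 room air rats (RA-RA, 8 of litter 4RARA and 7 of litter 6RARA), and in right ventricle from 14 altitude rats and 11 room air rats, of which 7 came from litter 4RARA and 4 from litter 6RARA. Total counts per library ranged from 9.71e+06 to 2.39e+07 in altitude lung, 1028679 to 21.9e+06 in room air lung, 9.54e+06 to 1.63e+07 in altitude right ventricle and 6116006 to 1.41e+07 in room air right ventricle. Males numbered 7 of 14 and 7 of 15 in the lung groups, and 7 of 14 and 5 of 11 in the right ventricle groups. The Y-linked genes Ddx3 and Eif2s3y lay at 69.8 to 153 CPM and 54.5 to 88.9 CPM in the 14 male lung libraries. Neither exceeded 0.212 CPM in the 15 female ones.

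Several libraries stood apart. Both libraries of animal 4HH37 held transcripts of the other tissue: its lung library held right ventricle transcripts at a median of 16.9% of their ventricular level (26 genes), and its ventricle library held lung transcripts at 35.2% of their lung level (14 genes). The 4 right ventricle libraries of litter 6RARA had RIN values of 5.8 to 7.4 and intergenic shares of 17.3 to 22.5%, against 9.28 to 12.3% in litter 4RARA. Their Myh6, the main myosin heavy chain of rat heart, lay at 5060 to 6798 CPM, against 15850 to 22640 CPM in litter 4RARA. The same 4 libraries held Sftpc, a surfactant protein of lung, at 87.7 to 685 CPM, and the female ones reached 9.83 CPM of Ddx3. Alb, the albumin gene of liver, lay at 13.6 to 1191 CPM in these 4, against 0.144 to 3.96 CPM in ventricle libraries of litter 4RARA. Among lung libraries, 6RARA66 had 59.2% intergenic reads, and the median Spearman correlation with other lung libraries was 0.803 for 4HH39 and 0.882 for 6RARA68.

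The lung comparison asks how life-long low oxygen pressure changed gene expression in the organ whose vessels meet it first. Ntrk2, the receptor of brain-derived neurotrophic factor, rose from 56.5 ± 24.3 CPM (SD, n = 15) in room air to 303 ± 130 CPM (SD, n = 14) at altitude, a log2 fold change of 2.44 ± 0.26 (SE). Slc26a10, of an anion transporter family, rose from 2.10 ± 2.10 to 14.1 ± 8.83 CPM (SD, n = 15 and 14). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell from 56.6 ± 32.9 to 12.5 ± 5.52 CPM, and Abcb1b, a P-glycoprotein drug transporter, fell from 31.4 ± 14.3 to 9.23 ± 4.46 CPM (SD, n = 15 and 14). Col6a4, a collagen VI chain, fell by 1.49 ± 0.18 on the log2 scale (SE). Each of these 5 genes lay on its fitted side of the room air median in 14 of 14 altitude libraries. This is a description and not a test, since the naming rule chose the genes from these libraries.

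**Figure D1:**
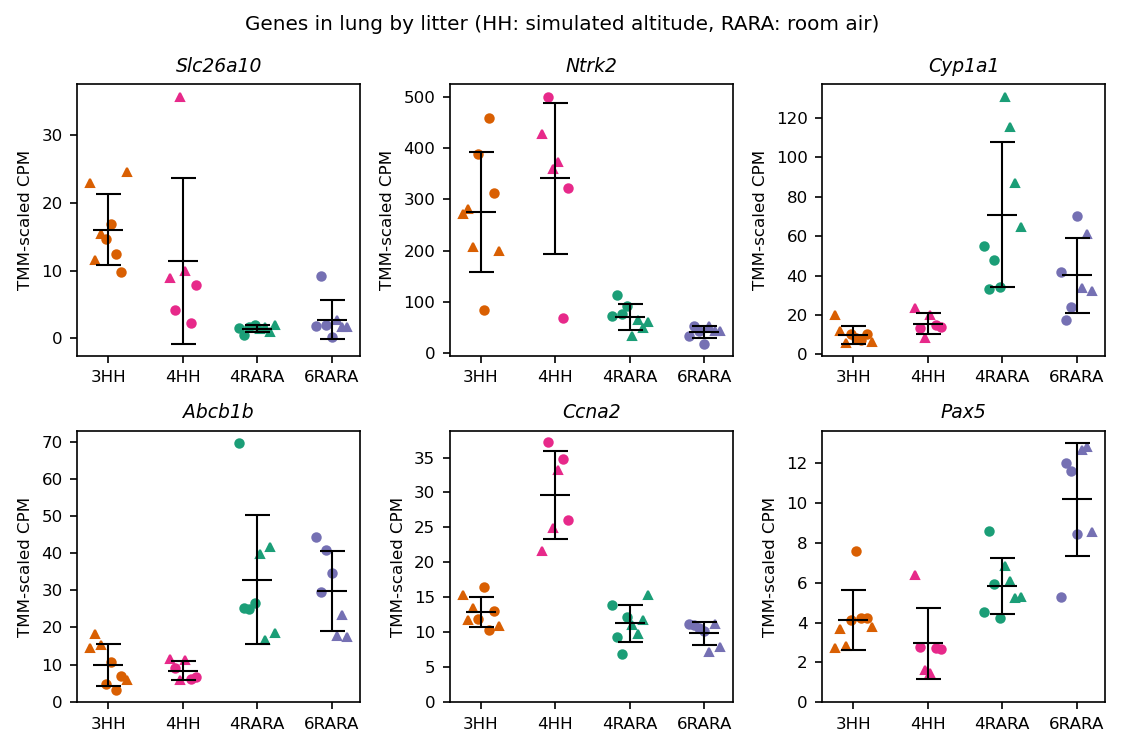
Expression of 6 genes in lung in CPM, with each library as a point (triangles are males, circles females) and bars for the mean and SD of each of the 4 litters. Ntrk2 and Slc26a10 were higher and Cyp1a1 and Abcb1b lower in both altitude litters (3HH and 4HH), whereas Ccna2 stood apart in litter 4HH.

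In the edgeR test, 242 of 12115 genes were called in lung, 105 higher and 137 lower at altitude, 182 of them by at least 1.5-fold. This balance turned over by litter. It was 252 higher and 97 lower without 3HH, 645 and 586 without 4RARA, 81 and 156 without 4HH, and 88 and 129 without 6RARA. Adjusted p values were 6.7e-07 for Ntrk2, 2.35e-06 for Slc26a10 and Cyp1a1, 4.5e-06 for Col6a4 and 5.67e-05 for Abcb1b. In rn6, Slc26a10 lies on chromosome 7 from 70459532 to 70467453, Ntrk2 on chromosome 17 from 5934690 to 6244627 and Cyp1a1 on chromosome 8 from 62472087 to 62478117. Called in all 4 fits that left out a litter were 33 of the 242 genes, 14 higher and 19 lower, a summary chosen after seeing the data. Each such fit counted littermates as replicates and left a treatment with a single litter, so it cannot separate exposure from litter. The 33 genes included Ntrk2, Slc26a10, Cyp1a1, Abcb1b and Col6a4. Among them also were Gpihbp1, which anchors lipoprotein lipase on capillary endothelium (1.53 ± 0.26, SE), the mast cell protease gene Mcpt1l1 (1.72 ± 0.21), Lyve1 of lymphatic endothelium (−1.06 ± 0.15), the transcription factor Sox9 (−1.45 ± 0.27), the chemokine receptor Cxcr4 (−0.58 ± 0.10) and the serotonin transporter Slc6a4 (−0.61 ± 0.13).

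The other largest rises of the naming rule were Tcap, a sarcomere protein (2.80 ± 0.54, SE), Cox8b, a muscle subunit of cytochrome c oxidase (2.22 ± 0.59), and Dbp, a clock output factor (1.86 ± 0.41). Its other largest falls were Cd177, a neutrophil surface protein (−2.06 ± 0.40), and Bpifb1, secreted in airways (−1.67 ± 0.36). Tcap and Cox8b are heart and muscle genes, and without animal 4HH37 they gave 1.81 (adjusted p = 0.000407) and 0.84 (adjusted p = 0.132). Cardiac muscle markers as a list had 1 called member of 12, Tcap, with Myl4 at 1.30 ± 0.40 (adjusted p = 0.0877), and 11 adjusted over the list alone. Their median was 2.84, and the camera adjusted p of 3.2e-05 became an adjusted p of 0.368 with an estimated correlation. Without 4HH37 the median was 0.998 (camera adjusted p = 1.31e-06) and without litter 4HH it was 1.21 (3.73e-08), with 1 called member and unadjusted p of 0.0339 and 0.0184 with an estimated correlation.

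Genes of the cell cycle were higher in altitude lung as a list: all 22 had positive log2 fold changes, with a median of 0.542. Of them 3 rose over all genes tested, the mitotic kinase Aurkb (1.35 ± 0.26, SE), the cyclin Ccna2 (0.92 ± 0.19) and Bub1 (0.63 ± 0.17), 19 did not pass, and 19 rose adjusted over the list alone. The camera adjusted p was 1.93e-13, with an adjusted p of 0.124 with an estimated correlation. Without litter 4HH the median was 0.00203, and Ccna2 came to 0.28 (adjusted p = 0.376), whereas Aurkb gave 1.79 (adjusted p = 0.00019). Without litter 3HH, Aurkb came to 0.45 (adjusted p = 0.234) and the cell cycle median to 1.02, with 15 genes called (camera adjusted p = 2.8e-39, and unadjusted p = 4.04e-05 with an estimated correlation). Erythroid and globin markers, of another proliferating lineage, also moved by litter: none of 9 passed with all litters (median 0.426), 4 were higher without 3HH (median 1.31, camera adjusted p = 3.37e-08, and unadjusted p = 0.0175 with an estimated correlation), and without 4HH the median was −0.866 (4.26e-05 and 0.0697). Hbb, a globin gene, lay at 899 to 16310 CPM in the 6 lung libraries of 4HH and at 134 to 2739 CPM in the 8 of 3HH.

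Clock genes moved in opposite directions in lung, as the arms of the circadian oscillator do over a day. Of 14 members 6 rose, namely Tef (0.86 ± 0.17, SE), Per3 (1.54 ± 0.32), Per2, Dbp, Ciart and Nr1d2, 2 fell, namely Arntl (−1.09 ± 0.26) and Nfil3, and 6 did not pass. Adjusted over the list alone, 9 rose and 3 fell. The camera adjusted p was 0.000893, with an adjusted p of 0.154 with an estimated correlation. The list gave a camera adjusted p of 0.539 without litter 3HH (median 0.551). Per3 and Dbp gave adjusted p values of 0.107 and 0.194 without litter 6RARA, and of 0.229 and 0.201 without litter 3HH.

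Marker lists of B cells and of T and NK cells and the RT1 genes were lower in altitude lung and mast cell markers higher, none of them with an estimated correlation (adjusted p of 0.0624 for B cells, the lowest). Pax5 (−1.10 ± 0.22, SE) and Pou2af1 (−0.65 ± 0.15), transcriptional regulators of B cells, fell among 10 B and plasma cell markers, 8 fell adjusted over the list alone, and all 10 were negative. Among 32 RT1 genes, which encode rat MHC molecules, 4 fell, RT1-M2 (−1.08 ± 0.20), RT1-DOb (−0.72 ± 0.15), RT1-A1 and RT1-Db1, and RT1-O1 rose (1.14 ± 0.28), with 13 lower and 1 higher adjusted over the list alone. Of 19 T and NK cell markers, Tbx21 (−0.88 ± 0.22) and the perforin gene Prf1 (−0.63 ± 0.17) fell, the same number as adjusted over the list alone. Of 9 mast cell markers 4 rose, the proteases Tpsb2 (0.94 ± 0.19), Cma1 (1.14 ± 0.29) and Tpsab1 and the IgE receptor subunit Ms4a2. For mast cells, 5 rose and 2 fell adjusted over the list alone. Camera adjusted p values were 1.39e-08 for B cells, 2.88e-09 for RT1, 0.00014 for T and NK cells and 0.00178 for mast cells. With an estimated correlation the adjusted p values were 0.0624, 0.124, 0.396 and 0.0959. The T and NK median of −0.269 came to 0.0448 without litter 3HH (camera adjusted p = 0.767) and −0.1 without 4RARA (0.549). It came to −0.548 without 4HH (4.75e-11), −0.465 without 6RARA (6.19e-07) and −0.523 without the 3 libraries of low correlation (1.17e-08), with unadjusted p of 0.0152, 0.0612 and 0.0451 with an estimated correlation. The B cell list was called without any 1 litter (camera adjusted p of 0.0165 or less, and unadjusted p of 0.00318 to 0.137 with an estimated correlation), and the mast cell list gave a camera adjusted p of 0.194 without 4RARA (median 0.893).

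Immediate early genes fell with Klf4 (−0.81 ± 0.15, SE), Ier2 (−0.50 ± 0.13) and Cyr61 among 18 members, of which 16 were negative and 8 fell adjusted over the list alone (camera adjusted p = 1.57e-07, and adjusted p = 0.0959 with an estimated correlation). Endothelial markers split: Emcn rose (0.60 ± 0.15), whereas Plvap, a protein of capillary diaphragms (−0.73 ± 0.15), and the angiopoietin receptor gene Tek fell among 15, with 1 higher and 2 lower adjusted over the list alone. Their camera adjusted p was 0.0312, and the adjusted p was 0.381 with an estimated correlation. That list call was lost with any 1 litter left out (camera adjusted p of 0.0876 without 3HH, 0.191 without 4HH, 0.167 without 4RARA and 0.247 without 6RARA) and without 4HH37 (0.0606). Klf2, a flow-responsive endothelial factor, fell by 0.99 ± 0.21 on the log2 scale (SE) and was the only called member of 15 pulmonary hypertension risk genes, where Kcna5 gave 0.82 ± 0.29 (adjusted p = 0.153). That list's median of 0.0719 and mean of 0.0301 were positive and its camera direction was down. Slc6a4 was the only called one of 26 vasoactive signalling genes, whose median was 0.0012, mean 0.0113 and camera direction down, with Gucy1a3 at 0.44 ± 0.14 (adjusted p = 0.1). Adjusted over the list alone, 1 vasoactive gene was higher and 1 lower, and 1 risk gene lower, and the camera adjusted p values were 0.942 and 0.809.

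Of 10 airway epithelial markers none passed and 3 fell adjusted over the list alone, with Foxj1, the regulator of motile cilia, at −0.80 ± 0.28 (SE, adjusted p = 0.158) and Cyp2f4 at −0.87 ± 0.31 (adjusted p = 0.166). The list's camera adjusted p was 7.8e-05 (median −0.759), with an adjusted p of 0.368 with an estimated correlation, and without litter 6RARA the median was 0.16. Respiratory chain genes (25 of 26 positive, median 0.224) and fatty acid oxidation genes (21 of 25 positive, median 0.141) had no called member and 0 adjusted over the list alone. Their camera adjusted p values were 0.0248 and 0.0312, with adjusted p values of 0.785 and 0.766 with an estimated correlation. The lowest p there were of Cox6a2 (2.81 ± 0.87), Cox5b (0.40 ± 0.23), Fabp3 (3.39 ± 1.04) and Acadl (0.43 ± 0.15). Without animal 4HH37 Cox6a2 came to 0.61 and Fabp3 to 0.81, and the camera adjusted p values of the lists were 0.572 and 0.281. Without litter 4HH the respiratory chain had a median of −0.152 (camera adjusted p = 0.0174) and fatty acid oxidation −0.0124 (0.608), and without 3HH the medians were 0.562 (2.93e-08) and 0.393 (0.000986). None of these 3 calls held with an estimated correlation, at unadjusted p of 0.409, 0.147 and 0.203.

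Genes that the hypoxia-inducible factors are known to induce did not move as a list in lung. None of 22 HIF target genes passed over all genes and 1 was lower adjusted over the list alone: Adm, the adrenomedullin gene, gave −0.76 ± 0.22 (SE, adjusted p = 0.0581) and Pfkfb3 0.80 ± 0.27 (adjusted p = 0.134). The camera adjusted p was 0.546. Of 16 glycolysis genes none passed on either scale (camera adjusted p = 0.241), with Ldhb at 0.88 ± 0.32 (adjusted p = 0.177) and Gapdh at 0.35 ± 0.18 (adjusted p = 0.407). Without litter 3HH 2 glycolysis genes were called and the median was 0.295 (camera adjusted p = 0.000869, and unadjusted p = 0.0644 with an estimated correlation). That fit kept the lung library of 4HH37, which held right ventricle transcripts, and Ldhb and Gapdh are abundant in altitude right ventricle (2557 and 4152 CPM). Over the alternatives Ldhb ran from 0.11 to 1.72 and Gapdh from −0.07 to 0.78 on the log2 scale. At the unadjusted scale 1623 of the 12115 genes had p under 0.05.

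Among interferon response genes 1 of 23 fell, Ifit1 (−2.44 ± 0.56, SE), with Bst2 at −0.26 ± 0.18 (adjusted p = 0.589), and without litter 4RARA Ifit1 gave −0.18 (adjusted p = 0.814). That list's median was 0.101, its mean −0.0414 and its camera direction down. Camera called it higher without litter 3HH (median 0.367, adjusted p = 0.00836) and lower without 4HH (−0.337, 0.000314), without 6RARA (−0.071, 0.014) and without the 3 libraries of low correlation (−0.0997, 0.0121). With an estimated correlation the unadjusted p were 0.266, 0.203, 0.378 and 0.386. Cd177 was the 1 neutrophil marker of 12 that fell, with Csf3r at −0.32 ± 0.22 (adjusted p = 0.59). Vsig4 of resident macrophages (0.91 ± 0.22) was the 1 of 16 macrophage and monocyte markers that rose, with Cd14 at −0.41 ± 0.13 (adjusted p = 0.0974). Adjusted over the list alone, 1 interferon gene and 1 neutrophil marker were lower, and 3 macrophage markers were higher and 1 lower. No member passed on either scale among genes of BMP and TGF-beta signalling (24), extracellular matrix (27), heat shock (25), NRF2 targets (20) and cholesterol synthesis (19), nor among markers of smooth muscle (15), erythroid cells (9), other tissues (thymus, skeletal muscle and fat, 6), alveolar type 2 cells (15) and alveolar type 1 cells (12). Camera adjusted p values of these 13 lists lay between 0.118 and 0.977. For extracellular matrix the median of 0.0667 and the camera direction differed in sign, as for smooth muscle (0.02) and, inversely, cholesterol synthesis (−0.00585).

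Exposure in lung was confounded with litter: limma voom with litter as a random effect called 10 genes, and edgeR on counts summed over each of the 4 litters called 0, with 323 genes at an unadjusted p under 0.05. Library batch as a covariate left 156 calls, the fits within batches 1 and 2 called 0 (813 at an unadjusted p under 0.05) and 2, females alone gave 11, DESeq2 gave 480, and 508 genes were called without 4HH39, 6RARA66 and 6RARA68.

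In right ventricle, which pumps against the vessels of the lung, the largest rises of the naming rule were Nppa, atrial natriuretic peptide, from 23.7 ± 14.7 to 80.9 ± 76.5 CPM, and Tnni1, the troponin I isoform of the fetal heart, from 1.48 ± 0.59 to 4.85 ± 1.85 CPM (SD, n = 11 and 14). Log2 fold changes were 1.73 ± 0.48 and 1.68 ± 0.25 (SE), and 10 and 14 of the 14 altitude libraries lay above the room air median. Arntl, the clock factor BMAL1, fell from 53.9 ± 33.4 to 10.2 ± 6.69 CPM (−2.43 ± 0.39, SE), with 14 of 14 altitude libraries below the room air median. As in lung, these library counts are a description and not a test, since the naming rule chose the genes from the same libraries. RT1-T24-3, of the MHC, fell from 171 ± 136 to 48.7 ± 20.3 CPM. Endothelial, interferon and RT1 genes were lower as lists by camera, each with an adjusted p of 0.417 with an estimated correlation. Most of the size of these falls came with litter 6RARA, whose 4 libraries stood apart.

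**Figure D2:**
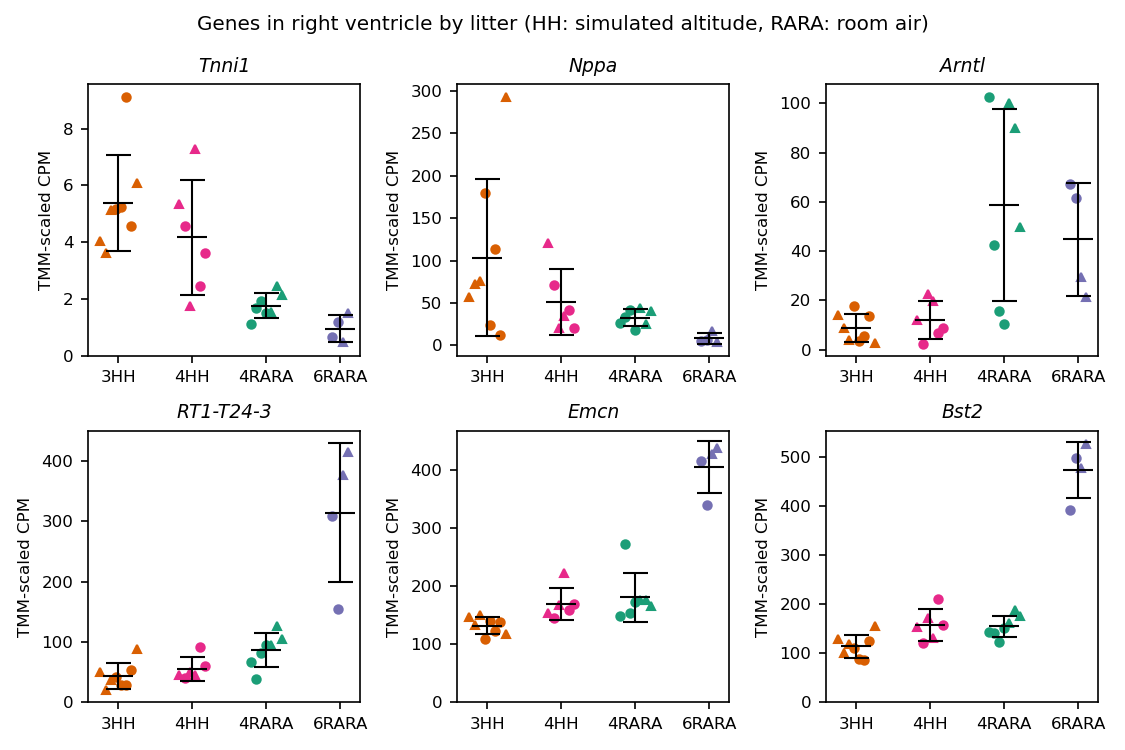
Expression of 6 genes in right ventricle in CPM, with each library as a point (triangles are males, circles females) and bars for the mean and SD of each of the 4 litters. Tnni1 was higher and Arntl lower in both altitude litters, whereas RT1-T24-3, Emcn and Bst2 stood apart in litter 6RARA.

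The edgeR test called 343 of 11298 genes in right ventricle, 94 higher and 249 lower at altitude, and 270 by at least 1.5-fold. With scaling by library size alone, 562 were called, 63 higher and 499 lower. Rises outnumbered falls with RIN as a covariate (31 and 20), with voom and quality weights (327 and 271) and without litter 4RARA (3413 and 3105). Falls outnumbered rises by DESeq2 (586 and 210) and without litter 6RARA (12 and 6) or 4HH (31 and 21). Adjusted p values were 0.004 for Tnni1, 0.00449 for Arntl, 0.0104 for RT1-T24-3 and 0.0473 for Nppa. In rn6, Tnni1 lies on chromosome 13 from 52625441 to 52636257, Nppa on chromosome 5 from 164808407 to 164809716 and Arntl on chromosome 1 from 178039063 to 178137471. The other largest rises of the naming rule were the clock gene Per3 (1.59 ± 0.34, SE), Sec14l5 (1.53 ± 0.31) and Ccdc92 (1.26 ± 0.28). Its other largest falls were the cytochrome P450 gene Cyp2e1 (−1.76 ± 0.39), Mill1, related to MHC class I (−1.71 ± 0.41), and Myoc, the myocilin gene (−1.62 ± 0.42). Over 24 alternatives, Cyp2e1 ran from −3.02 to −0.28 and was called in 11. Mill1 ran from −2.52 to −0.67 and Myoc from −3.11 to −0.72, each called in 9. Of the rises, Per3 and Sec14l5 were called in 11 and Ccdc92 in 12.

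Markers of endothelium fell with Emcn (−0.85 ± 0.19, SE), the capillary carbonic anhydrase gene Car4 (−0.89 ± 0.22), Pecam1, Tek and Cldn5 called among 15, all of them negative, and 13 fell adjusted over the list alone. Interferon response genes had 4 lower members of 22, Ifi27l2b (−1.44 ± 0.29), Bst2, which tethers virions (−1.04 ± 0.24), Ifi27 and Rsad2, and 14 adjusted over the list alone. Of 25 RT1 genes 4 fell, RT1-T24-3 (−1.78 ± 0.32), RT1-S3 (−0.99 ± 0.25), RT1-T24-4 and RT1-M3-1, and 15 adjusted over the list alone. Medians were −0.667, −0.645 and −0.634, with camera adjusted p values of 1.52e-08, 4.16e-10 and 5.5e-10. With an estimated correlation the adjusted p was 0.417 for each. Over the 62 genes of the 3 lists the median of −0.647 went to −0.134 without litter 6RARA and to −1.25 without litter 4RARA. List by list, without 6RARA, endothelial markers gave 0.0287 (camera adjusted p = 0.7), interferon genes −0.155 and RT1 genes −0.211 (camera adjusted p = 0.00727 for both, and unadjusted p of 0.358 and 0.244 with an estimated correlation), and without the 5 libraries of low correlation −0.148 (camera adjusted p = 0.239), −0.142 (0.00817) and −0.278 (0.000174), the last 2 with unadjusted p of 0.392 and 0.0981 with an estimated correlation. Without litter 6RARA, Emcn gave −0.30 (adjusted p = 0.497), Bst2 −0.23 (adjusted p = 0.689) and RT1-T24-3 −0.82 (adjusted p = 0.194).

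**Figure D3:**
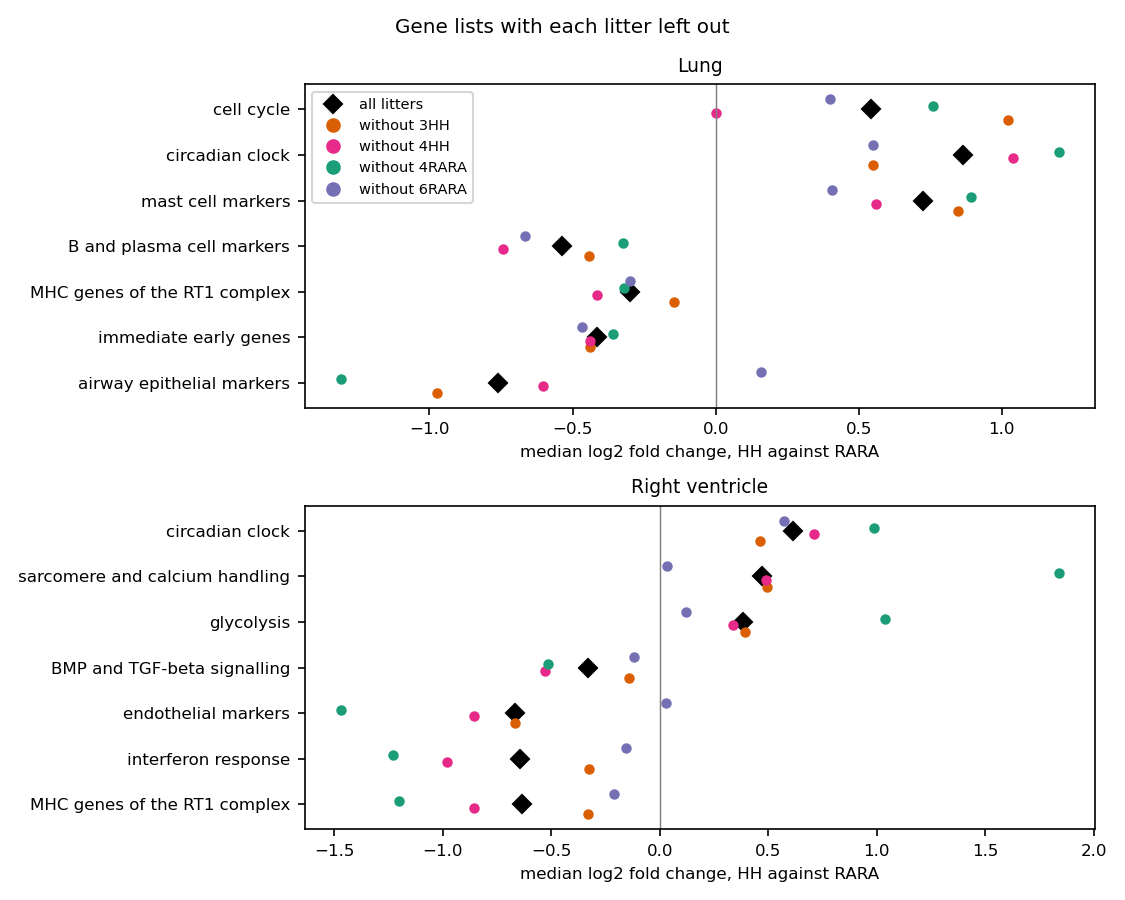
Median log2 fold change of altitude against room air for 7 gene lists in lung and 7 in right ventricle, with all litters (diamonds) and with each of the 4 litters left out (circles). In lung the cell cycle median lay at 0.00203 without 4HH and the airway median at 0.16 without 6RARA, and in right ventricle the endothelial median lay at 0.0287 without 6RARA.

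BMP and TGF-beta signalling had 4 lower members of 24, the BMP targets Id3 (−0.95 ± 0.23, SE) and Id1 (−1.28 ± 0.32), the BMP effector Smad1 (−0.65 ± 0.16) and Ltbp1, and 8 adjusted over the list alone. Its camera adjusted p was 0.000974, with an adjusted p of 0.417 with an estimated correlation. The water channel gene Aqp1 (−1.14 ± 0.25), 1 of 15 pulmonary hypertension risk genes, fell, with Klf2 at −1.12 ± 0.33 (adjusted p = 0.0588), and the clearance receptor of natriuretic peptides, Npr3 (−0.75 ± 0.19), fell as 1 of 25 vasoactive genes, with Aplnr at −0.89 ± 0.30 (adjusted p = 0.0914). Adjusted over the list alone, 5 risk genes and 1 vasoactive gene were lower. Camera adjusted p values were 0.0455 and 0.0351, with an adjusted p of 0.517 for both with an estimated correlation. Immediate early genes fell with Ier2 (−0.87 ± 0.24) and Klf4 (−1.17 ± 0.33) among 17, 5 adjusted over the list alone, at a camera adjusted p of 0.00113 and an adjusted p of 0.517 with an estimated correlation. Without litter 6RARA, Id3 gave −0.16, Aqp1 −0.30 and Ier2 −0.04, and Klf4 turned to 0.09, with adjusted p values of 0.73, 0.459, 0.964 and 0.925. Camera adjusted p values without 6RARA were 0.7 for vasoactive, 0.773 for risk and 0.773 for immediate early genes, with 0.0275 for BMP and TGF-beta signalling (median −0.117, and unadjusted p = 0.255 with an estimated correlation). They were, without 3HH, 0.382, 0.429 and 0.122 for the same 3 lists and 0.328 for BMP and TGF-beta signalling.

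Of sarcomere, glycolysis, respiratory chain and fatty acid oxidation genes no member rose, and camera called the 4 lists higher, none of them with an estimated correlation (adjusted p of 0.417 or more). All 21 sarcomere and calcium handling genes were positive (median 0.469), with Mybpc3 at 0.40 ± 0.16 (SE, adjusted p = 0.156) and Myh6 at 0.59 ± 0.24 (adjusted p = 0.157). All 16 glycolysis genes were positive (median 0.385), with Eno1 at 0.33 ± 0.11 (adjusted p = 0.1) and Eno3 at 0.60 ± 0.22 (adjusted p = 0.118). Respiratory chain genes had a median of 0.383 and 1 called member of 26, Cox4i2, an oxygen-responsive subunit isoform, which fell (−0.70 ± 0.19), with Ndufb8 at 0.55 ± 0.26 (adjusted p = 0.221). Fatty acid oxidation had a median of 0.29 over 25 genes, with Cpt1a at 0.21 ± 0.10 (adjusted p = 0.201) and Acot2 at 0.37 ± 0.18 (adjusted p = 0.235). The counts were 0, 0, 1 lower and 0 adjusted over the list alone. Camera adjusted p values were 1.58e-07 (sarcomere), 1.11e-05 (glycolysis), 3.49e-06 (respiratory chain) and 0.000345 (fatty acid oxidation), with adjusted p values of 0.463, 0.417, 0.517 and 0.52 with an estimated correlation. Without litter 6RARA the medians were 0.0328, 0.123, 0.00297 and −0.0894, with camera adjusted p values of 0.773, 0.0976, 0.773 and 0.0301, the last for a fall that was not called with an estimated correlation (unadjusted p = 0.271).

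Atrial cardiomyocyte markers had 2 higher members of 10, Nppa and Dkk3 (0.64 ± 0.17, SE), with 4 higher and 1 lower adjusted over the list alone, and a camera adjusted p of 0.0287, with an adjusted p of 0.44 with an estimated correlation and camera adjusted p values of 0.7 without 6RARA and 0.0707 without 3HH. In the hypertrophy and fetal programme Nppa and Tnni1 rose and Ctgf, a matricellular growth factor gene, fell (−0.90 ± 0.21) among 14, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0959). Tnni1 gave 1.44 without litter 6RARA (adjusted p = 0.0218), 1.83 without 4HH (0.00146), 2.29 without 4RARA (8.94e-05) and 1.43 without 3HH (0.178). Nppa gave 1.26 without 6RARA (adjusted p = 0.462), 1.09 without 3HH (0.398) and 2.08 without 4HH (0.0692).

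Clock genes in right ventricle moved like those in lung: Tef (1.16 ± 0.23, SE), Per3 and Per2 rose and Arntl and Npas2 (−1.31 ± 0.29) fell among 14, with 8 higher and 4 lower adjusted over the list alone. The camera adjusted p was 0.0192 and the adjusted p was 0.417 with an estimated correlation. Without litter 3HH it was 0.275 (median 0.46) and without 4RARA 0.205 (median 0.985). Of 22 cell cycle genes the replication helicase genes Mcm2 (0.52 ± 0.09) and Mcm5 (0.91 ± 0.17) rose, 3 adjusted over the list alone, the median was −0.0626, the mean 0.0013 and the camera direction up (adjusted p = 0.319). Among 25 heat shock and unfolded protein genes Pdia6 (0.33 ± 0.08), Herpud1 (0.82 ± 0.20) and Sdf2l1, of the endoplasmic reticulum, rose, 3 also adjusted over the list alone, with median −0.0118, mean −0.203 and camera direction up (adjusted p = 0.132).

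HIF target genes went both ways in right ventricle. The glucose transporter gene Slc2a1 rose (0.50 ± 0.14, SE), Adm (−0.88 ± 0.21) and Ndrg1 (−1.06 ± 0.26) fell, and 18 of 21 did not pass, with 1 higher and 4 lower adjusted over the list alone. The median of 0.118 was positive, the mean of −0.0435 negative and the camera direction up (adjusted p = 0.802), and without litter 6RARA Adm gave −0.33 (adjusted p = 0.548) and Ndrg1 −0.19 (adjusted p = 0.707). Of 27 extracellular matrix genes Ctgf fell, with Sparc at −0.81 ± 0.23 (adjusted p = 0.055), and 2 were lower adjusted over the list alone (camera adjusted p = 0.298). No member passed over all genes among smooth muscle (15), erythroid (9), B cell (6), T and NK cell (18), neutrophil (6), macrophage (15), mast cell (9), other tissue (3) and lung epithelial markers (10), NRF2 targets (19) or cholesterol synthesis genes (19). Adjusted over the list alone, 4 smooth muscle markers and 1 mast cell marker were lower, and none of the other 9 lists had a member past the threshold. Camera adjusted p values of these 11 lists lay between 0.0516 and 0.959. The median and the camera direction differed in sign for mast cells (−0.0225) and lung epithelial markers (0.125). The mean of the latter was −0.0176, and that of mast cells was 0.0187.

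The right ventricle count depended on litters and libraries: 18 genes were called without litter 6RARA, 0 without 3HH, 52 without 4HH, 6518 without 4RARA, 34 without the 5 libraries of low correlation (the 4 of 6RARA and 4HH37), and 531 without animal 4HH37 alone. RIN as a covariate, with the doubtful RIN of 3HH28 as labelled, left 51 calls, library batch as a covariate 23, males alone 2 and batch 2 alone 4, and DESeq2 called 796. Counts of 0 came from voom with litter as a random effect, edgeR on sums per litter, edgeR within batch 1, edgeR in females alone and edgeR without 3HH, with 729, 46, 326, 1506 and 1417 genes at an unadjusted p under 0.05.

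Comparing the tissues, fold changes of 10986 genes tested in both correlated across genes at a Pearson r of 0.284 (Spearman 0.292), where genes are not independent replicates. With lung of males set against right ventricle of females, which are different animals, r was 0.148, and with the sexes reversed 0.236. Called in both tissues were 30 genes, 26 of them in the same direction, 5 higher and 21 lower. The tissues are not independent: they come from the same litters, and the deviations of the 2 tissues of an animal correlated at a mean r of 0.25 over 25 animals. Lower in both were the Notch ligand gene Dll4 (−0.85 ± 0.16 in lung and −1.08 ± 0.23 in right ventricle, SE), the Notch targets Nrarp and Hes1, Cxcr4, Klf4, Ier2, Sox9, Igfbp3 and Tek. Higher in both were Per2, Per3, Tef, Mmp23 and Reep1. Emcn, Pparg and Tcf15 were higher in lung and lower in right ventricle, and Glod5 the reverse. These genes, other than those named above, were chosen after their values were seen. The right ventricle side of this overlap depended on litter. Without 6RARA, 8 of the 343 right ventricle calls were called and 335 kept their sign, with Klf4 at 0.09 (adjusted p = 0.925). Of the 343, 0 were called in all 4 fits that left out a litter, so the 26 genes are not a stable shared set.

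**Figure D4:**
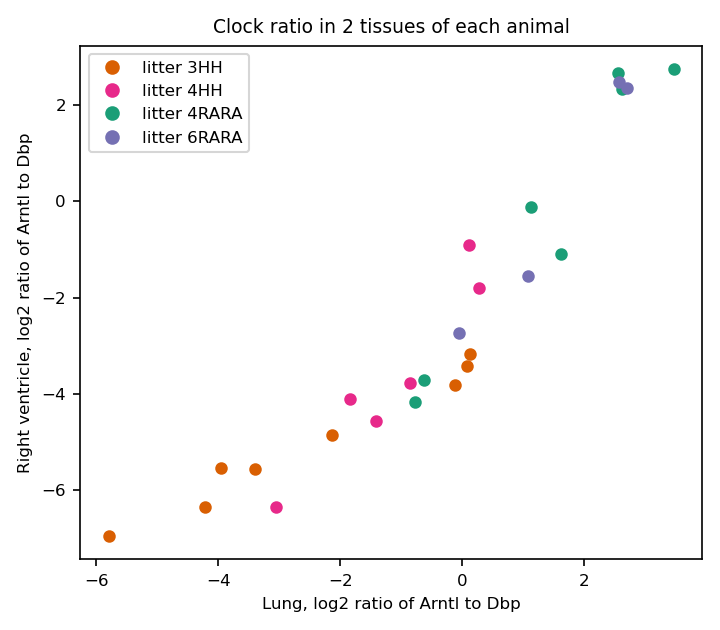
Log2 ratio of Arntl to Dbp in lung (x axis) and right ventricle (y axis) of the 25 animals with both tissues, colored by litter. The ratios of the 2 tissues of an animal rose together within the 14 altitude and within the 11 room air animals.

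The phase marker of the clock, the log2 ratio of Arntl to Dbp, was shared by the tissues of an animal. Within altitude animals (n = 14) the lung and right ventricle ratios correlated at a Pearson r of 0.897 (permutation p = 2e-05, adjusted 4e-05) and a Spearman rho of 0.947 (permutation p = 1e-05, the smallest that the permutations can give, adjusted 4e-05). Within room air animals (n = 11) r was 0.97 (permutation p = 5e-05, adjusted 7e-05) and rho 0.909 (permutation p = 0.0004, adjusted 0.0004). Without the 2 animals farthest from the median lung ratio, r was 0.857 and 0.94. These 4 coefficients are the family adjusted together. Within library batches of at least 6 animals of 1 treatment, r was 0.923 (n = 7, exact permutation p = 0.00774) and 0.877 (n = 6, exact permutation p = 0.0236) in altitude animals of lung batches 1 and 2. It was 0.993 (n = 6, exact permutation p = 0.00139) in altitude animals of ventricle batch 2 and 0.956 (n = 6, exact permutation p = 0.00833) in room air animals of ventricle batch 1. The other batches held fewer animals of 1 treatment. Lung ratios ran from −5.79 to 0.269 at altitude and from −0.774 to 3.47 in room air.

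The test of tissue by treatment asked which genes responded differently in the tissues, and called 119 of 11723, 37 with a more positive difference in right ventricle and 82 with a more negative one. The more positive were led by Glod5 (1.80 ± 0.31, SE), Abcb1b (1.67 ± 0.35), Cish, a brake on cytokine signalling (1.54 ± 0.26), Ddo (1.44 ± 0.36) and the retinoic acid enzyme gene Aldh1a3 (1.38 ± 0.35). Cish went from 35.8 ± 13.6 to 27.96 ± 7.27 CPM in lung and from 21.2 ± 9.80 to 48.2 ± 11.5 CPM in right ventricle (SD). The more negative were led by Slc26a10 (−3.38 ± 0.43), Cyp2e1 (−2.20 ± 0.42), Gpihbp1 (−2.08 ± 0.37), Ntrk2 (−2.06 ± 0.49) and Dmbt1 (−1.95 ± 0.44). Gpihbp1 went from 31.9 ± 17.0 to 91.1 ± 50.8 CPM in lung and from 119.9 ± 80.7 to 79.7 ± 14.7 CPM in right ventricle (SD). Groups held 14 and 15 lung and 14 and 11 right ventricle libraries, and adjusted p values of the 10 genes lay between 1.3e-06 and 0.0298. With the replicate block of animal 114 genes were called, 66 of them among the 119, without litter 3HH 23, without 6RARA 25, without 4HH 63, without 4RARA 3474, without libraries of low correlation 62, without animal 4HH37 179 and by DESeq2 219.

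Between the sexes, edgeR called no gene outside X and Y in lung, where 4 genes were called, 2 higher and 2 lower in males, and 470 had an unadjusted p under 0.05. The lowest p outside X and Y were of Ostn (−0.80 ± 0.20, SE, adjusted p = 0.597), Tnfsf13b (−0.67 ± 0.17), Cyp26b1 (0.99 ± 0.27), Inmt (−1.05 ± 0.31) and the heart gene Myl3 (4.85 ± 1.47), with adjusted p values of 0.884 for the last 4. Without animal 4HH37, Myl3 gave 0.58 (adjusted p = 0.905), and with RIN as a covariate Ostn passed (adjusted p = 0.0307). In right ventricle 5 genes were called, 2 higher and 3 lower in males, with 724 at an unadjusted p under 0.05. Evi2a (0.68 ± 0.15), Adh1 (1.91 ± 0.44), Fgg (3.34 ± 0.82), H19 (0.92 ± 0.24) and Ces1d (1.06 ± 0.27) had adjusted p values from 0.29 to 0.616. Without animal 4HH37, Fgg gave 2.15 and Ces1d 0.82 (adjusted p = 0.983 for both), Adh1 1.63 (0.511), Evi2a 0.67 (0.398) and H19 1.01 (0.177). Ddx3 was higher in males by a log2 difference of 12.3 ± 0.25 in lung and 7.64 ± 0.73 in right ventricle (SE). DESeq2 called 5 genes in lung and 15 in right ventricle, among the latter Evi2a (adjusted p = 0.0258), Adh1 (0.01) and Fgg (0.00783). Alb, the albumin gene of liver, reached 1191, 144 and 138 CPM in the male ventricle libraries 6RARA72, 6RARA71 and 4HH38. In female ventricle libraries it reached 18.7 CPM at most. Whether the differences of Adh1 and Fgg came from such libraries and not from sex was not tested.

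Whether altitude acted differently in males and females was tested as an interaction, and edgeR called 0 genes in lung and 0 in right ventricle. At an unadjusted p under 0.05 there were 761 and 365 genes, and DESeq2 called 9 and 0. Without the 3 lung libraries of low correlation edgeR called 2 in lung.

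Litters of 1 treatment differed in more genes than the treatments in 3 of 4 tests. In lung, the 5 genes of lowest p between 4HH and 3HH were Tk1, of thymidine salvage (1.04 ± 0.13, SE), the cyclins Ccnb2 (1.40 ± 0.19) and Ccna2 (1.19 ± 0.16) and Cdc20 (1.06 ± 0.15), higher in 4HH, and Ankrd6 (−0.76 ± 0.11), lower. In all 503 genes were called there, 344 higher and 159 lower in 4HH, 1005 by DESeq2, and 263 without animal 4HH37, 257 of them among the 503. Litter 6RARA had more Aldh1a7, an aldehyde dehydrogenase gene (5.13 ± 0.48), Krt14 of basal cells (3.20 ± 0.39), Smtnl2 (0.97 ± 0.11), Camk2n1 (0.82 ± 0.11) and Sgcb (1.23 ± 0.16) in lung than 4RARA, with 2550 genes called, 1232 higher and 1318 lower.

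In right ventricle, 4HH exceeded 3HH in the MHC class II genes RT1-Ba (1.01 ± 0.14, SE) and RT1-Da (0.95 ± 0.17), the chemokine gene Cxcl16 (0.72 ± 0.11) and Gzmk of cytotoxic lymphocytes (1.82 ± 0.31), with Tnnt3 lower (−1.002 ± 0.17). There 137 genes were called, 84 higher and 53 lower, 437 by DESeq2 and 61 with RIN as a covariate. Without animal 4HH37, whose ventricle library held lung transcripts, 72 were called, 54 of them among the 137, and RT1-Ba gave 0.86, RT1-Da 0.75, Cxcl16 0.68 and Gzmk 1.66, at adjusted p values from 0.00251 to 0.0165. The 4 libraries of 6RARA differed from those of 4RARA in 6802 genes (60.2%), 3356 higher and 3446 lower, led by Mccc2 of leucine breakdown (−2.88 ± 0.15), Tmx2 (−2.39 ± 0.13), Tmem182 (−3.33 ± 0.18), Ank1 (−2.97 ± 0.17) and Lrrc14b (−3.36 ± 0.20). Adjusted p values of the 20 litter genes lay at or below 0.00919.

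The deposited fold changes of the authors correlated with those computed here across genes at r = 0.871 in lung and 0.881 in right ventricle. The authors' table has 742 lung genes at a false discovery rate under 0.05, 311 higher and 431 lower, which include 241 of the 242 called here. It has 491 right ventricle genes, 195 higher and 296 lower, which include 261 of the 343. Directions of the shared genes were the same in both sources.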

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

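The counts under other splits of the samples, the fits of single genes without a litter and the RIN covariate were planned, and the tests of explanations, those that use these fits included, were chosen only after the result was seen.

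The treatment difference itself differed between right ventricle and lung in 119 genes, and those named were the ones with the widest differences. On the log2 scale, right ventricle minus lung, they were Glod5 at 1.80, Abcb1b at 1.67, Cish at 1.54, Ddo at 1.44 and Aldh1a3 at 1.38, and Slc26a10 at −3.38, Cyp2e1 at −2.20, Gpihbp1 at −2.08, Ntrk2 at −2.06 and Dmbt1 at −1.95. Among 100 splits, 4 gave as many genes as the real 119 (the real split included), with 435 as the highest other. These splits moved both tissues of an animal together and did not keep litters whole. They bear only on the placing of single animals, not of the 4 litters, which are the independent exposures. The count ran from 23 to 3474 with a litter left out, so the splits exclude neither chance nor litter as the source. Of 14 other settings run for each gene, Slc26a10 was called in 14, Abcb1b, Cish and Gpihbp1 in 13, Glod5, Cyp2e1 and Ntrk2 in 12, Aldh1a3 in 10, and Ddo (0.45 to 3.54) and Dmbt1 (−3.65 to −0.59) in 9.

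The splits of the treatment counts also broke up litters, so they bear only on the placing of single libraries and do not exclude chance between litters. In lung the real split gave 242 genes and the highest of the other 99 gave 1 (1 of 100 as many), and in right ventricle the real split gave 343 and the highest other 1695 (2 of 100). The split with 1695 had all 4 libraries of litter 6RARA on the room air side, which points to a structure of the samples. The 3 pairings of whole litters are too few for a share under 0.05: the real pairing gave 242 genes in lung against a highest other of 1019, and 343 in right ventricle against 1866, with 3 of 3 pairings giving as many. Those larger counts point to litter as a structure of the samples. For the sexes 3 of 100 splits gave as many in lung (4, highest other 19) and 3 of 100 in right ventricle (5, highest other 2303). With 0 genes for sex by treatment by edgeR (761 and 365 at an unadjusted p under 0.05, 9 and 0 by DESeq2), all 100 splits gave as many in each tissue, the highest other being 435 in lung and 3533 in right ventricle. Those high counts point to structure of the samples too. Between litters the real split was the 1 of 100 with as many genes in each test: 503 against 269 and 2550 against 0 in lung, 137 against 3 and 6802 against 2353 in right ventricle.

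Clock genes differed between the treatments in both tissues, though the list calls were lost with an estimated correlation (adjusted p of 0.154 in lung and 0.417 in right ventricle). A different time of day at sampling needs the lung and the heart of an animal to share a phase, and within each treatment the clock ratio of the tissues correlated at an r of 0.897 or more. With the ratio of the other tissue as a covariate, 2 of 13 clock calls kept p under 0.05, Arntl (−0.475 ± 0.203, SE) and Per3 (0.612 ± 0.286) in right ventricle. In lung Arntl went from −1.13 ± 0.267 to −0.124 ± 0.24. The times of sampling are a candidate explanation, and an effect of treatment on the clock cannot be told apart from it, since treatment may itself shift the phase.

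Endothelial, interferon and RT1 genes were lower in altitude right ventricle, at a median of −0.647 over 62 genes, though no list was called with an estimated correlation (adjusted p = 0.417 for each). Lung tissue in the room air pieces is argued against as the cause: lung epithelial markers did give −2.84 without animal 4HH37, but the share their levels give (0.615 to 4.82% in litter 6RARA) would move the 62 genes by −0.0153, against −0.687 observed without 4HH37. A lower share of cardiomyocytes in the room air pieces stays open. It was tested on the assumption that it raises every other cell type alike, and macrophage markers moved 0.765 above endothelial ones (95% interval 0.606 to 1.02). That interval, of 10000 resamples, does not cover the spread between the 4 litters, which are the independent exposures. Other values went with a lower share of cardiomyocytes: medians of smooth muscle (−0.232) and T and NK cell markers (−0.264) were negative and that of sarcomere genes was 0.469. Myh6 lay at 5060 to 6798 CPM in litter 6RARA, against 15850 to 22640 CPM in 4RARA. Without litter 6RARA the median was −0.134, and endothelial markers gave 0.0287, consistent with a property of those 4 libraries for this list, whereas interferon (−0.155) and RT1 genes (−0.211) were smaller falls that camera still called (adjusted p = 0.00727 for both) but not with an estimated correlation (unadjusted p of 0.358 and 0.244), so a part of theirs stays open. A linear effect of RIN is argued against as the whole cause: with RIN as a covariate, which took the count of called genes from 343 to 51, the median was −0.465 (quartiles −0.66 and −0.371), while other properties of the RNA, dissection and the litter's biology stay open.

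Cell cycle genes were higher in altitude lung as a list, at a median of 0.542, though 19 of 22 did not pass and the list call was lost with an estimated correlation (adjusted p = 0.124). Libraries apart by RNA length or depth are argued against as the cause, since the median was 0.545 without them. Without litter 4HH the median was 0.00203, so litter 4HH alone is a candidate source, with its parents and age untested. Without litter 3HH the median was 1.02, that of T and NK cell markers 0.0448 and that of B cell markers −0.444, which leaves lymphoid tissue in the pieces of 4HH open. Erythroid cells in those pieces stay open too: their markers had a median of 1.31 without 3HH, yet without 4HH they gave −0.866 while the cell cycle genes did not follow.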

How the results depend on the processing

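The alternatives by library batch, quality weights, libraries of low correlation, animal 4HH37, the clock covariate, animals with both tissues without a block and gene list tests with a litter left out were chosen after seeing the data, and the others before the data were examined. The cause was not tested for any change below.

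For lung at altitude (242 genes) DESeq2 gave 480, voom with litter as a random effect 10, counts summed per litter 0 by edgeR (323 at an unadjusted p under 0.05), females only 11, library batch as a covariate 156, batch 1 alone 0 by edgeR (813 at an unadjusted p under 0.05), batch 2 alone 2, quality weights 1069 and libraries of low correlation left out 508. The clock ratio as a covariate gave 82 over the animals with both tissues, where 211 were called without it. With a litter left out the count ran from 217 (6RARA) to 1231 (4RARA). The count stayed within 1.5 times for 2 other scalings, 2 other filters, no sex term, RIN as a covariate, RIN of at least 7, robust=FALSE, males only, animals with both tissues and animal 4HH37 left out.

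For right ventricle (343 genes) DESeq2 gave 796, library size only 562 (63 higher, 499 lower), RIN as a covariate 51, RIN of at least 7 gave 1, voom with litter as a random effect 0 (729 at an unadjusted p under 0.05), counts summed per litter 0 by edgeR (46), males only 2, females only 0 by edgeR (1506), library batch as a covariate 23, batch 1 alone 0 by edgeR (326), batch 2 alone 4, quality weights 598, libraries of low correlation left out 34, animal 4HH37 left out 531 and the clock ratio 1. With a litter left out the count ran from 0 (3HH, by edgeR, 1417 at an unadjusted p under 0.05) to 6518 (4RARA).

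For sex by treatment in lung (0 by edgeR, 761 at an unadjusted p under 0.05) DESeq2 gave 9 and libraries of low correlation left out 2. For 4HH against 3HH, DESeq2 gave 1005 and 4HH37 left out 263 in lung (503). In right ventricle (137) DESeq2 gave 437, 4HH37 left out 72 and RIN as a covariate 61. DESeq2 gave 15 for sex in right ventricle (5). The litter tests of right ventricle were not run without libraries of low correlation, which include all 4 of litter 6RARA there. Tissue by treatment (119) gave 219 by DESeq2, 62 without libraries of low correlation, 179 without 4HH37 and 23 (3HH) to 3474 (4RARA) with a litter left out. The replicate block of animal gave 114 over animals with both tissues, 66 of them among the 119, where no block gave 133, with 97 among the 119. The correlation of the tissues (0.284) was 0.148 with lung of males and right ventricle of females.

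Of the gene lists, camera called 12 of 29 in lung, against 0 with an estimated correlation and 6 by fry. The 6 were B and plasma cell (fry adjusted p = 0.00255) and mast cell markers (0.00807), immediate early (0.00995), RT1 (0.0142), cell cycle (0.0151) and clock genes (0.029). In right ventricle camera called 13 of 29, against 0 with an estimated correlation and 1 by fry, the clock list (adjusted p = 0.033). Neither camera nor fry was fitted with litter. Camera called 7 right ventricle lists without libraries of low correlation and 7 (6RARA) to 19 (4HH) with a litter left out. Directions of named genes called in the treatment comparisons reversed in 3 values: Ifit1 in lung within batch 1 (0.000717), and Klf4 in right ventricle without litter 6RARA (0.0935; with other litters left out down to −2.17, without 4RARA) and without libraries of low correlation (0.0878). For 30 named called lung genes 504 of 748 values were the same and 243 weaker, and for 31 of right ventricle 320 of 744 were the same and 422 weaker. Animal numbers do not pair the treatments, so pairing by number was not run, and pseudocounts did not apply to counts.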

Other observations

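The summaries, list tests and permutation tests of this part were chosen only after the result was seen. The edgeR tests of single genes, those without a litter included, were planned.

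Among the lung genes called with each of the 4 litters left out in turn were Ffar3, a receptor of short-chain fatty acids (3.43 ± 0.31, SE, log2), Fam181b (3.02 ± 0.27) and Resp18 of neuroendocrine cells (1.93 ± 0.26), higher at altitude, and the B cell adaptor gene Bank1 (−1.14 ± 0.17), lower. Right ventricle had 0 such genes by edgeR, of the 343 called with all litters. These fits leave a treatment with a single litter, so they cannot separate exposure from litter.

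Cyp1a1 was lower in altitude lung, while 8 other targets of the aryl hydrocarbon receptor had a median of −0.0334 and a camera p of 0.895. Dll4, Nrarp and Hes1 were lower in both tissues, while 20 other Notch pathway genes had camera p values of 0.286 in lung (median −0.0332) and 0.0381 in right ventricle (median −0.0295), the latter adjusted to 0.0763. Of these 20, Hey2 fell in lung (−0.58, adjusted p = 0.0486) and Jag1 (−0.84, adjusted p = 0.0281) and Dll1 (−0.80, adjusted p = 0.0303) in right ventricle.

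Of the 25 animals with both tissues, litter 6RARA contributed 4. Library batches 1, 2 and 3 held 7, 6 and 1 altitude and 4, 6 and 5 room air lung libraries, and 4, 6 and 4 altitude and 6, 4 and 1 room air right ventricle libraries. The mitochondrial share was 3.49 and 3.26% in altitude and room air lung (permutation p = 0.69) and in right ventricle altitude minus room air was −3.39 percentage points, against 34.3% in room air, a difference that did not pass (permutation p = 0.2, adjusted 0.4). The lung library of 4HH39 and that of 6RARA68 held relatively more short transcripts, with length slopes of −1.21 and −0.63.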
